A study of Homo sapiens with 15 samples.

How the data were processed

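RNA was sequenced from human natural killer (NK) cells, blood lymphocytes that kill infected or transformed cells, isolated as CD56+ CD3− cells from 3 donors. Each donor gave 1 library in each of 5 groups: fresh cells (day 0); cells after 16 h (day 1) in a low dose of IL-15 (1 ng/mL), in IL-12, IL-15 and IL-18 together (10, 50 and 50 ng/mL) or in 18/12/TxM, a trimeric fusion protein (38.8 nM); and cells exposed to 18/12/TxM for 16 h, washed and kept until day 6 in 1 ng/mL IL-15. The labels name Direct-zol RNA MicroPrep extraction, standard Illumina library preparation and total RNA; whether the libraries kept strand is not given in the sources used here. Samples were grouped by the submitters' labels, and the replicate number stands for the donor.

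The authors deposited 1 table of log2 CPM values, that is, each gene's read share scaled to a fixed library size (CPM) on a log scale with a small added value that keeps genes without reads finite. The submitters' processing notes name bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5, Salmon 0.8.2 and GRCh38, without the role or order of each. The lowest value was −5.11 in each of the 15 libraries, a CPM of 0.0289, and stood for 0 reads. When the values were turned back to CPM and the added part was taken off, 100% of the values up to 1000 reads were whole multiples of what 1 read is worth, within 0.1 of a read, so the reads per gene could be recovered. Recovered totals ran from 9153478 to 37661641 reads per library, and the 3 libraries of day 6 were the smallest, with at most 10829668 reads. There a CPM of 1 is about 10 reads, so values under a log2 CPM of 0 rest on few reads.

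The table held 34343 lines and 21 columns of values. Of these, 6 columns matched no given sample and were not analysed here. After 130 repeated lines were taken out, 34213 gene identifiers remained, of which 34209 matched GENCODE release 29 (Ensembl 94, GRCh38), the source of all coordinates and gene types given here. A further 128 genes on the Y chromosome or of the X inactivation centre were left out so that no value could describe a person, which left 34085 genes. Of these, 19353 had a log2 CPM of at least 0 in at least 3 libraries and were tested; 15983 of them are protein-coding and 2558 had a mean log2 CPM of at least 6, called well-expressed genes here.

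Differences were tested on the deposited log2 scale with limma 3.58.1 (R 4.3.3) in 1 model over all 15 libraries with a term per group, a mean-variance trend and 10 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Fold changes are on the log2 scale of the deposited values, whose added part understates the change of genes with few reads. All adjusted p-values of single genes are from this limma model, and n = 3 donors in each group. Altogether 36 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 36 lists within each comparison: 24 lists of NK cell functions and states and 12 lists of other blood cell types or RNA classes. Counts of list members were made over all genes tested and again adjusted over the list alone. The comparisons, the test, the lists, the rule for named genes and 31 alternative settings were fixed before the data were examined. Another 5 alternatives were added after the data had been seen.

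The rule for named genes took, per comparison, the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 over the groups compared and the same sign in 3 of 3 donors. It left out sex-linked, KIR, mitochondrial and pseudogenes, antigen receptor segments, HLA genes outside the lists and clone-style names. Per list it added the 4 members with the smallest adjusted p and any member given as not passing, and a gene named in 1 comparison may be named in the others. Of those, genes with near-identical copies, such as CCL3, were not named.

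The same-donor pairing was checked on the deviations of each library from its group mean. The 30 pairs of libraries from the same donor had correlations of 0.005 to 0.284 (median 0.138), and 60 pairs from different donors had a median of −0.072. Since the labels tie the numbers to donors, the fit with the donor as a block is given beside a list result wherever it changes the call. Replicates differed beyond sampling noise in each pair, so none was merged. The tests were tried on simulated data with the real spread before use; with 100 genes raised or lowered 2-fold and 100 changed 4-fold, the self-test recovered 27.4% and 62.2% for IL-12/15/18 against low-dose IL-15, and 33.2% and 57.4% for 18/12/TxM against IL-12/15/18. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

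Alternatives changed the filter on low values, the pseudocount, the scaling between libraries, the variance prior, the library weights, the samples in the fit, the donor block and the list test, and left out each donor and each library in turn. The added ones were centring on well-expressed genes, limma-voom on the recovered reads with median-ratio library factors, IFNG left out of the library totals, libraries thinned to the smallest total, and well-expressed genes alone. Since CPM gives each gene as a share of its library, a gene group that takes a larger share lowers all others; the scaling alternatives measure how far calls rest on this.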

Results

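Gene expression was measured by RNA sequencing in blood NK cells of 3 donors, in 15 libraries that form 5 groups of 3: fresh cells, cells after 16 h with low-dose IL-15, with IL-12/15/18 or with the fusion protein 18/12/TxM, and cells at day 6 after 18/12/TxM. IL-12, IL-15 and IL-18 together are used to make "memory-like" NK cells, and 18/12/TxM was built to deliver the signals of these cytokines in 1 molecule. The libraries held 9153478 to 37661641 recovered reads. Median centring, used throughout as the other scaling, sets the median tested gene of each library to the same value. Coordinates are on GRCh38. Where no second count follows a count of list members, the count adjusted over the list alone was the same. The p of a list is camera's, adjusted over 36 lists. With well-expressed genes alone, the lists of other cell types and of histone genes kept too few members to be tested. In that setting the p was adjusted over the remaining lists.

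Many genes of low abundance were lower in the activated groups at day 1 and higher at day 6, so the scaling between libraries sets how many genes count as higher or lower. The median log2 fold change over the 19353 genes tested was −0.98 for IL-12/15/18 and −0.95 for 18/12/TxM, each against low-dose IL-15. It was −0.02 for low-dose IL-15 against fresh cells, 1.73 for 18/12/TxM at day 6 against day 1 and 0.72 for day 6 against fresh cells. Over the 2558 well-expressed genes the medians were −0.30, −0.26, 0.12, 0.22 and 0.08. Counts are therefore given on the deposited scale and after median centring. Median centring moves all genes of a library by the same value, although the shift was smaller in well-expressed genes. Calls that lists of well-expressed genes, such as ribosomal protein genes, gain after it can therefore come from the centring itself. Where median centring turned the balance of rises and falls, they are also given with well-expressed centring, which sets the median well-expressed gene of each library to the same value and was added after the data had been seen. The genes named in these Results as risen or fallen kept their sign after median centring.

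**Figure D1:**
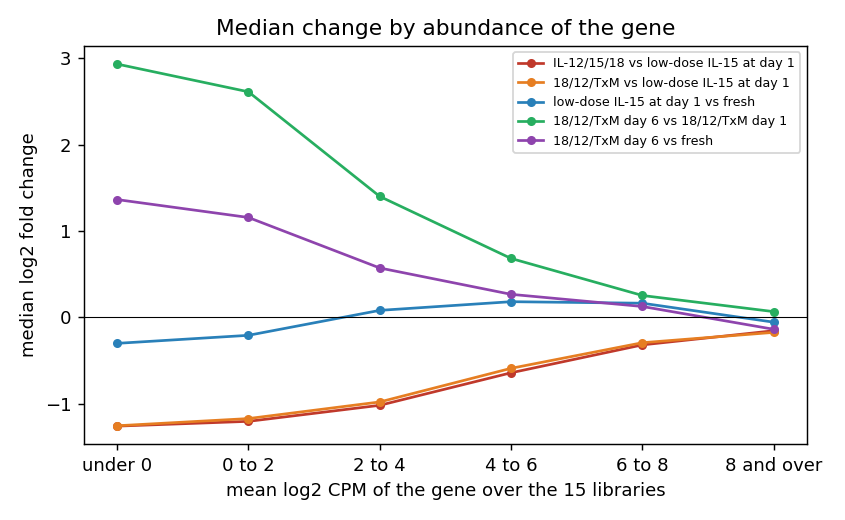
Median log2 fold change (y axis) of genes grouped by mean log2 CPM over the 15 libraries (x axis), with a line for each of 5 comparisons. Genes under a log2 CPM of 0 lay at −1.26 for both activated groups at day 1 and at 2.93 for day 6 against day 1, and genes of 8 and over at −0.16, −0.17 and 0.07. Genes under 0 were tested only if at least 3 libraries reached 0, which favours genes high in 1 group, such as day 6.

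Activation with IL-12/15/18 was compared with low-dose IL-15 to find what the cytokine combination changed in 16 h. NK cells given IL-12/15/18 carried far more mRNA of several secreted cytokines, and IFNG, the gene of interferon gamma (chromosome 12, 68154768 to 68159747), went from a mean log2 CPM of 5.05 ± 1.97 (SD, n = 3) to 16.61 ± 1.16 (SD, n = 3). Its log2 fold change was 11.56 (SE 0.68, limma adjusted p = 1.45e-08), and it made up 12.6% ± 10.7 (SD, n = 3) of the reads after activation, between 5.38% and 24.9%. Lymphotoxin alpha, LTA (chromosome 6, 31572054 to 31574324), rose by 7.16 on the log2 scale, and IL2RA (chromosome 10, 6010689 to 6062370), the alpha chain of the IL-2 receptor, rose by 6.12. The surface molecule CD52, at a log2 CPM of 8.70 ± 0.12 (SD, n = 3) with low-dose IL-15, was at 3.42 ± 0.92 (SD, n = 3) after IL-12/15/18.

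Of 32 secreted cytokines and chemokines measured, 12 rose and 2 fell (adjusted p = 2.01e-14), and after median centring 18 rose and 0 fell. Besides IFNG and LTA these included CSF2, the gene of GM-CSF (log2 fold change 5.57), IL26 (3.85) and LIF (3.11). Of 25 STAT5 and STAT3 targets and SOCS family genes, 14 rose and 2 fell (adjusted p = 1.34e-16), and after median centring 21 and 0. Of 31 NF-kB pathway targets, 12 rose and 5 fell (adjusted p = 4.08e-14), and 23 and 1 after median centring. ICAM1 (3.22), GADD45B (3.08) and TRAF1 (2.34) were among the rises. Genes of growth and metabolism rose as groups. Of 24 glycolysis genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 3.08e-25), led by HK2 (4.13), PKM (3.15) and ENO1 (2.53). Of 33 ribosome biogenesis genes 25 rose and 1 fell (26 and 1 adjusted over the list alone, adjusted p = 9.49e-36), among them NOP16 (2.31) and DDX21 (2.13). The unfolded protein response had 19 rises and 0 falls among 26 genes (20 and 1 adjusted over the list alone, adjusted p = 1.19e-24), with the chaperone HSPA5 at 1.74. Heat shock and chaperone genes had 13 rises and 2 falls among 20 (adjusted p = 2.13e-17), with HSP90AB1 at 2.12. Cholesterol and fatty acid synthesis had 16 rises and 2 falls among 30 (18 and 2 adjusted over the list alone, adjusted p = 4.01e-16), with MSMO1 at 1.59. Amino acid transport and one-carbon metabolism had 13 rises and 5 falls among 23 (adjusted p = 8.11e-14), with MTHFD2 at 2.80. After median centring these 6 lists had 22, 32, 26, 16, 25 and 17 rises, and 0 falls except 1 for amino acid transport. The 9 calls of this paragraph held with an estimated correlation. With well-expressed genes alone 3 of them were lost: cytokines and chemokines (median −0.15, adjusted p = 0.222), STAT5 and STAT3 targets (0.79, adjusted p = 0.113) and amino acid transport (0.96, adjusted p = 0.0635).

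Receptors moved both ways. LAG3 (6.00), CD274, the gene of PD-L1 (3.80), SLAMF1 (4.18), TNFRSF9, the gene of 4-1BB (4.08), and IL23R (4.40) rose, as did granzyme B, GZMB (2.83). KLRG1 (−3.90), CD160 (−3.90), TYROBP (−2.96), SLAMF6 (−3.27) and KIT (−4.17) fell. Of 21 cytotoxic granule and death ligand genes 6 rose and 9 fell, 10 and 3 after median centring and 6 and 8 with well-expressed centring. The median (−0.41) and mean (−0.44) of this list were negative while camera placed it above other genes (adjusted p = 0.0472). That call was lost with an estimated correlation (adjusted p = 0.527 with an estimated correlation) and with the donor block (adjusted p = 0.0522). Of 30 activating and costimulatory receptors 7 rose and 15 fell, 11 and 6 after median centring and 7 and 13 with well-expressed centring. Here too the median (−1.11) and mean (−0.48) were negative and the test was up (adjusted p = 0.0264; adjusted p = 0.524 with an estimated correlation and 0.130 with the donor block). Cytokine receptors had 7 rises and 12 falls among 29 (7 and 14 adjusted over the list alone, 8 and 4 after median centring, 8 and 9 with well-expressed centring) and made no call (adjusted p = 0.113). Inhibitory receptors had 5 rises and 11 falls among 21, 6 and 7 after median centring, and made no call either (adjusted p = 0.443). Of 36 lymphocyte transcription factors 11 rose and 17 fell (11 and 18 adjusted over the list alone, 17 and 9 after median centring, 11 and 14 with well-expressed centring, adjusted p = 0.110). BATF (2.62) rose, and TCF7 (−4.36), KLF2 (−4.26) and BCL11B (−3.02) fell.

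Of 26 quiescence and recirculation genes 1 rose and 23 fell (1 and 24 adjusted over the list alone), with a median of −2.39, and 2 and 20 after median centring. The list was lower than other genes (adjusted p = 2.31e-07; adjusted p = 0.0781 with an estimated correlation). S1PR1, the receptor that guides lymphocytes out of tissues, was at −4.08 and the interleukin-7 receptor gene IL7R at −4.45. Of 21 CD56 dim subset genes 2 rose and 16 fell (2 and 17 adjusted over the list alone), with a median of −3.59, and 3 and 13 after median centring (adjusted p = 0.00248; adjusted p = 0.524 with an estimated correlation). FGFBP2 (−5.08), SPON2 (−5.57) and the fractalkine receptor gene CX3CR1 (−4.54) were among them. CD56 bright subset genes had 1 rise and 9 falls among 20, 4 and 6 after median centring (adjusted p = 0.436). Tissue homing and adhesion genes had 4 rises and 14 falls among 25 (4 and 15 adjusted over the list alone), 6 and 6 after median centring, 4 and 12 with well-expressed centring (adjusted p = 0.861). Of the chemokine receptors CXCR3 (−5.71) and CXCR4 (−5.02) fell and CCR1 (2.98) rose. Of 45 interferon-stimulated genes 3 rose and 25 fell on the deposited scale, with IFIT2 at −3.40, 10 rose and 7 fell after median centring and 4 rose and 20 fell with well-expressed centring (adjusted p = 0.617). Of 8 MHC class II presentation genes 0 rose and 6 fell, 0 and 3 after median centring (adjusted p = 0.113; adjusted p = 0.527 with an estimated correlation and 0.0204 with the donor block). Cell cycle genes had 9 rises and 18 falls among 48 and a median and mean of −0.09. After median centring 25 rose and 0 fell, 12 and 10 with well-expressed centring, and the test was up (adjusted p = 0.000163; adjusted p = 0.0621 with an estimated correlation). MYC rose by 2.52, and so did the cell cycle inhibitor CDKN1A (4.40). Apoptosis regulators had 7 rises and 7 falls among 27, 16 and 1 after median centring, 9 and 5 with well-expressed centring (adjusted p = 5.11e-05; adjusted p = 0.0510 with an estimated correlation). Oxidative phosphorylation had 6 rises and 6 falls among 31 (6 and 4 adjusted over the list alone), 27 and 0 after median centring, 13 and 1 with well-expressed centring (adjusted p = 3.41e-06; adjusted p = 0.332 with an estimated correlation).

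Over all genes 10854 of 19353 differed between IL-12/15/18 and low-dose IL-15, with 1130 higher and 9724 lower, after median centring 5763, with 4165 higher and 1598 lower, and with well-expressed centring 8160, with 1667 higher and 6493 lower. Among well-expressed genes 513 were higher and 1075 lower on the deposited scale. The count without replicate 1 was 6443.

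**Figure D2:**
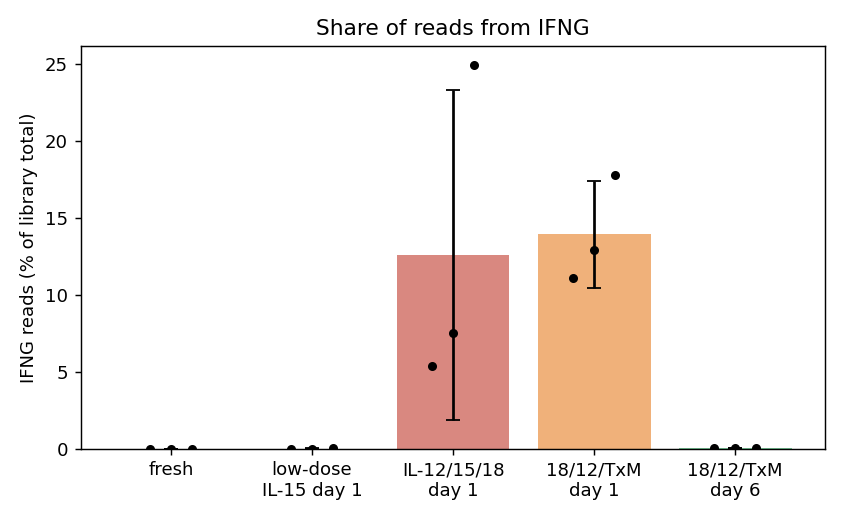
IFNG reads as a percent of each library's recovered reads (y axis) in the 5 groups (x axis); bars show the mean of 3 libraries, error bars the SD and points the libraries. The mean was 12.6% after IL-12/15/18 and 13.9% after 18/12/TxM at day 1, against 0.00526% with low-dose IL-15 and 0.0118% at day 6.

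The fusion protein 18/12/TxM was compared with low-dose IL-15 in the same way. It raised IFNG by 12.00 on the log2 scale (SE 0.68, limma adjusted p = 8.71e-09), to a mean log2 CPM of 17.06 ± 0.35 (SD, n = 3) and 13.9% ± 3.48 (SD, n = 3) of the reads. IL2RA (6.53), LTA (6.28) and CSF2 (6.11) rose, and so did RGS16, a regulator of G protein signalling (5.70), the ATP-gated channel gene P2RX5 (5.67), the metalloprotease ADAM19 (5.32), GPR84 (5.15) and the lipid transporter MFSD2A (5.07). FCRL6 (−7.03), DPEP2 (−6.09), CMKLR1 (−5.61), FCMR (−5.48) and KLF2 (−5.39), the transcription factor of quiescent lymphocytes, fell. LAG3 (5.89), CD274 (4.46), TNFRSF9 (4.68), SLAMF1 (4.16), EBI3 (4.45), IL26 (4.63), IL23R (4.30) and IL12RB2, a chain of the IL-12 receptor (1.88), were higher, and GZMB rose by 2.58.

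Of 32 cytokines and chemokines 12 rose and 2 fell (11 and 2 adjusted over the list alone, adjusted p = 2.57e-12). STAT5 and STAT3 targets had 15 rises and 2 falls among 25 (adjusted p = 1.04e-16), and NF-kB targets 15 and 5 among 31 (adjusted p = 1.82e-13). Of 24 glycolysis genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, adjusted p = 9.46e-23). Of 33 ribosome biogenesis genes 29 rose and 1 fell (adjusted p = 8.58e-40). NOP16 (2.55), HK2 (4.18), PKM (3.19), MTHFD2 (2.92), HSPA5 (1.77), HSP90AB1 (2.29) and MYC (2.93) rose within their lists. The unfolded protein response had 18 rises and 1 fall among 26 (adjusted p = 7.09e-22), and heat shock genes 13 and 1 among 20 (adjusted p = 4.39e-17). Cholesterol and fatty acid synthesis had 16 rises and 2 falls among 30 (18 and 2 adjusted over the list alone, adjusted p = 1.28e-14). Amino acid transport had 13 and 5 among 23 (adjusted p = 1.21e-13). After median centring these 9 lists had 17, 22, 23, 23, 32, 24, 17, 23 and 17 rises and at most 1 fall each. Cell cycle genes had 11 rises and 14 falls among 48 (11 and 13 adjusted over the list alone), with a median of 0.03 and a mean of 0.00. After median centring 25 rose and 0 fell, 14 and 10 with well-expressed centring, and the test was up (adjusted p = 4.68e-05). Apoptosis regulators had 8 rises and 7 falls among 27, 18 and 1 after median centring (adjusted p = 1.49e-05). These 11 calls held with an estimated correlation. With well-expressed genes alone 5 of them were lost: cytokines and chemokines (median −0.42, adjusted p = 0.357), STAT5 and STAT3 targets (0.81, adjusted p = 0.126), amino acid transport (1.13, adjusted p = 0.0615), cell cycle genes (0.44, adjusted p = 0.0841) and apoptosis regulators (0.43, adjusted p = 0.330). Oxidative phosphorylation had 8 rises and 4 falls among 31 (7 and 4 adjusted over the list alone), 26 and 0 after median centring (adjusted p = 8.37e-07; adjusted p = 0.285 with an estimated correlation).

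Quiescence genes had 1 rise and 22 falls among 26 (1 and 23 adjusted over the list alone), 1 and 20 after median centring, with a median of −2.34 (adjusted p = 1.67e-07; adjusted p = 0.0744 with an estimated correlation). S1PR1 was at −4.39 and TCF7 at −4.04. CD56 dim subset genes had 1 rise and 17 falls among 21, 3 and 13 after median centring, with a median of −3.92 (adjusted p = 0.000388; adjusted p = 0.453 with an estimated correlation). CX3CR1 was at −5.17 and FGFBP2 at −4.95. Of 45 interferon-stimulated genes 3 rose and 27 fell (4 and 29 adjusted over the list alone), 9 and 15 after median centring (adjusted p = 0.179), with IFIT2 at −3.75. Of 8 MHC class II genes 0 rose and 6 fell, 0 and 2 after median centring (adjusted p = 0.123; adjusted p = 0.521 with an estimated correlation and 0.0227 with the donor block). Cytotoxic granule genes had 5 rises and 10 falls among 21 (5 and 11 adjusted over the list alone), 9 and 3 after median centring, 6 and 8 with well-expressed centring (adjusted p = 0.149). Activating receptors had 7 rises and 15 falls among 30, 9 and 6 after median centring, 7 and 14 with well-expressed centring (adjusted p = 0.0895). Markers of T cells, which the CD3− gate excludes, had 0 rises and 10 falls among 11, 0 and 2 after median centring (adjusted p = 0.0778; adjusted p = 0.453 with an estimated correlation and 0.0287 with the donor block). After IL-12/15/18 they had 0 rises and 8 falls (0 and 9 adjusted over the list alone), 0 and 3 after median centring (adjusted p = 0.0988; adjusted p = 0.524 with an estimated correlation and 0.0476 with the donor block).

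In all, 10767 genes differed between 18/12/TxM and low-dose IL-15, 1255 higher and 9512 lower, 6004 after median centring, 4238 higher and 1766 lower, and 8387 with well-expressed centring, 1784 higher and 6603 lower. Among well-expressed genes 541 were higher and 1044 lower on the deposited scale, and the count without replicate 3 was 6115.

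**Figure D3:**
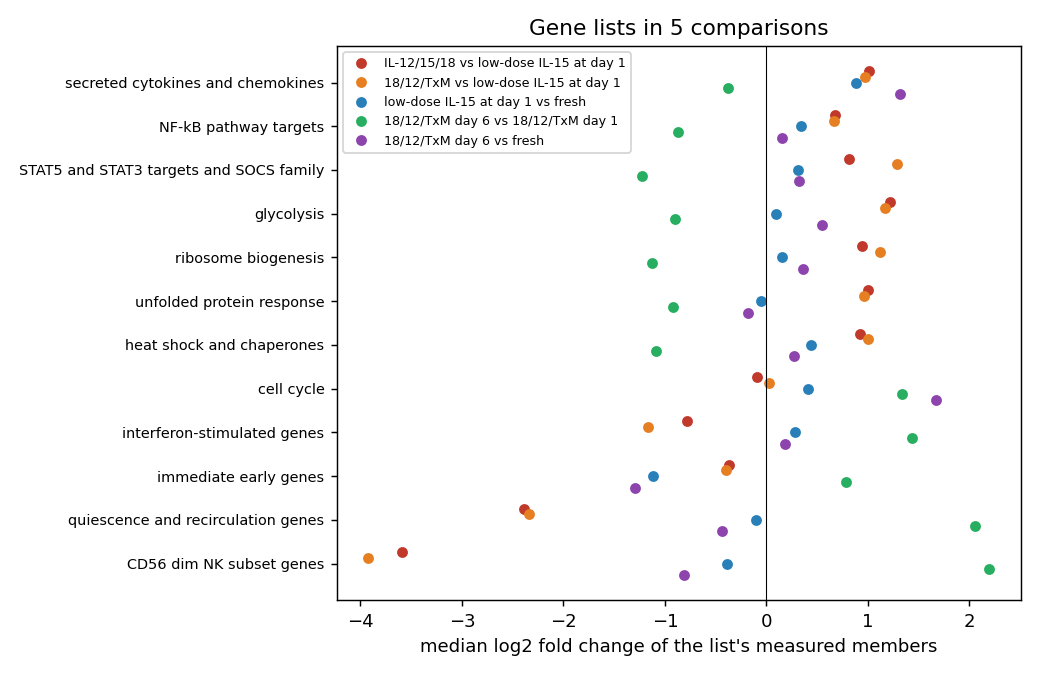
Median log2 fold change (x axis) of the measured members of 12 gene lists (y axis) in 5 comparisons, as points of separate colours, on the deposited scale; several lists with medians near the all-gene shift change sign after median centring. Ribosome biogenesis lay at 0.95 and 1.12 in the activated groups against low-dose IL-15 and at −1.12 for day 6 against day 1, and CD56 dim subset genes at −3.59, −3.92 and 2.20, with the same signs after median centring.

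Whether the fusion protein acted like the separate cytokines was asked by comparing 18/12/TxM with IL-12/15/18 directly; their doses are given as nM and ng/mL and were not matched here. No gene passed the test: the count was 0 of 19353 in limma, 0 after either centring and 0 with limma-voom on the recovered reads. An unadjusted p under 0.05 was met by 426 genes (324 with limma-voom), where 968 would by chance, but by 1232 with array weights, 1152 without replicate 3, 1055 without IL-12/15/18 day 1 replicate 3, 743 without 18/12/TxM day 1 replicate 3, 697 after thinning, 677 without replicate 1 and 652 without 18/12/TxM day 1 replicate 1. With pseudocounts of 1 and 4 the number was 100 and 73, and with only the 2 groups in the model 145. It was 722 of 32455 genes with no filter, 146 of 13261 with the stricter filter and 7 of 2558 with well-expressed genes alone. IFNG differed by 0.45 (95% interval −0.99 to 1.89), IL2RA by 0.41 (−0.51 to 1.33), GZMB by −0.25 (−0.83 to 0.34) and LAG3 by −0.11 (−1.30 to 1.09). The members with the smallest p in their lists were CMPK2, an interferon-stimulated gene (−1.77, −2.68 to −0.86), which passed when adjusted over the list alone, LTB, lymphotoxin beta (−1.24, −2.24 to −0.23), KLF2 (−1.12, −2.10 to −0.15), EBI3 (1.23, −0.07 to 2.53) and NCR3, the gene of NKp30 (−1.11, −2.51 to 0.29), all with an adjusted p of 1.00.

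The 95% interval of the difference lay within 1 log2 unit of 0 for 10003 genes (51.7%) and for 2470 of the 2558 well-expressed genes (96.6%), so for the rest a 2-fold difference was not excluded. No list held a member that passed over all genes. At the preset correlation camera placed 4 lists lower with 18/12/TxM. These were interferon-stimulated genes (median −0.25, adjusted p = 9e-05), CD56 dim genes (−0.25, adjusted p = 0.0105), immediate early genes (−0.20, adjusted p = 0.0443) and erythroid markers (−0.62, adjusted p = 0.0207). Ribosome biogenesis (0.18, adjusted p = 5.16e-07) and ribosomal protein genes (0.08, adjusted p = 0.0337) were placed higher. For these 6 lists, in this order, the adjusted p was 0.959, 0.959, 0.959, 0.734, 0.734 and 0.959 with an estimated correlation. Without replicate 3 the limma test called 1 gene, TNFSF4, the gene of OX40 ligand (log2 fold change 2.18, adjusted p = 0.0257). Without IL-12/15/18 day 1 replicate 3 it called TNFSF4 (1.92, adjusted p = 0.0219) and IL21R, the interleukin-21 receptor gene (1.58, adjusted p = 0.0461). These genes were named after their values had been seen.

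Across genes, which are not independent replicates, the log2 fold changes of the 2 treatments against low-dose IL-15 had a Pearson r of 0.896 and a covariance of 0.951. In 100 draws, unchanged groups and the controls they share were all simulated from the spread within groups. These draws gave a median r of 0.499 (0.268 to 0.724) and a median covariance of 0.112 (0.0501 to 0.237), a difference in covariance of 0.839. Both treatments called 1074 genes higher, against 73.3 for independent lists and at most 1 in the simulations, and 8113 genes lower, against 4779 and at most 0. The simulated groups had no effect and so few calls to share, and their counts cannot weigh the overlap. In opposite directions 0 genes were called. After median centring 3869 were higher and 1309 lower with both, against 912 and 146 for independent lists. The 3 control libraries cannot be split into parts of 2, so part of the excess may come from the shared controls.

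**Figure D4:**
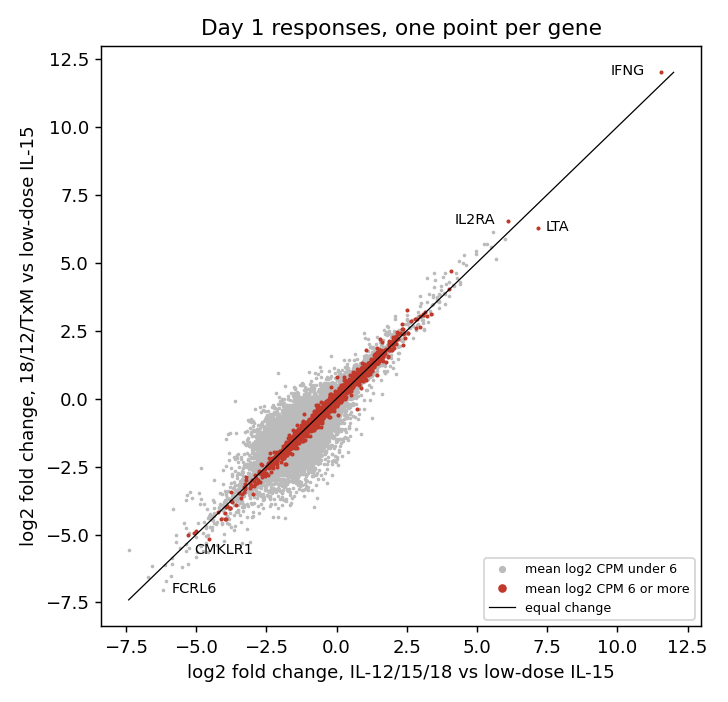
Log2 fold change of each of 19353 genes with IL-12/15/18 (x axis) and with 18/12/TxM (y axis), each against low-dose IL-15 at day 1; red points are the 2558 genes with a mean log2 CPM of at least 6, and the line marks equal change. Pearson r was 0.896 over all genes and 0.992 over the red points.

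The effect of 16 h in low-dose IL-15, the control of the activated cells, was measured against fresh cells. ZFP36, the gene of an mRNA-decay factor (chromosome 19, 39406813 to 39409412), went from a log2 CPM of 9.08 ± 0.24 (SD, n = 3) to 5.63 ± 0.18 (SD, n = 3), a log2 fold change of −3.45 (limma adjusted p = 9.4e-07). DUSP1 (−4.02), JUNB (−3.12), JUN (−2.75), NR4A2 (−2.92), CSRNP1 (−2.44), AREG, the gene of amphiregulin (−3.21), and SERTAD3 (−2.56) fell as well. GPR171 (3.49), the chemokine receptors CXCR6 (3.05) and CCR1 (2.63), IL2RA (2.97), TNFAIP8L2 (2.91) and the stem cell factor receptor KIT (2.75) rose, as did the chemokine CXCL10 (4.96). IFNG, at 0.98 (adjusted p = 0.494), and LAG3, at −0.46 (adjusted p = 0.743), did not pass.

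Of 24 immediate early genes 3 rose and 14 fell (3 and 15 adjusted over the list alone), 2 and 13 after median centring, with a median of −1.11 (adjusted p = 3.38e-10; adjusted p = 0.360 with an estimated correlation). With well-expressed genes alone the median of this list was 0.03 (adjusted p = 0.676). FOS had a log2 fold change of −5.11 (adjusted p = 0.0086, and 0.107 without replicate 1, 0.0711 without replicate 2 and 0.0610 with robust eBayes). EGR2 went the other way at 3.95 (adjusted p = 0.00142, and 0.0768 without replicate 1 and 0.0727 without replicate 2). Of 12 replication-dependent and other histone genes 0 rose and 5 fell (0 and 6 adjusted over the list alone, 0 and 5 after median centring), with HIST2H2BE at −3.28 (adjusted p = 3.03e-06; adjusted p = 0.360 with an estimated correlation). Of 36 ribosomal protein genes 0 rose and 2 fell, 0 and 0 after median centring and 0 and 17 with well-expressed centring, with a median of −0.32 (adjusted p = 3.38e-10; adjusted p = 0.476 with an estimated correlation). Cytokines and chemokines had 5 rises and 1 fall among 32 (9 and 1 adjusted over the list alone, 4 and 1 after median centring, adjusted p = 0.0164; adjusted p = 0.457 with an estimated correlation). Cytokine receptors had 7 and 1 among 29 (8 and 2 adjusted over the list alone, 5 and 0 after median centring, adjusted p = 0.0247; adjusted p = 0.476 with an estimated correlation). Interferon-stimulated genes had 6 and 1 among 45 (9 and 1 adjusted over the list alone, 6 and 1 after median centring, adjusted p = 0.0267; adjusted p = 0.679 with an estimated correlation). Cell cycle genes had 6 and 1 among 48 (4 and 1 after median centring, adjusted p = 0.00312; adjusted p = 0.385 with an estimated correlation). CD56 dim genes had 0 rises and 2 falls among 21 (0 and 3 adjusted over the list alone, 0 and 2 after median centring, adjusted p = 0.0164; adjusted p = 0.679 with an estimated correlation). Of 21 cytotoxic genes the death ligands FASLG (1.87) and TNFSF10, the gene of TRAIL (1.94), were the 2 that rose, and 1 fell (2 and 1 after median centring, adjusted p = 0.693). Of 25 STAT5 and STAT3 targets 6 rose and 2 fell (10 and 2 adjusted over the list alone, 5 and 2 after median centring), with CISH at 2.98 (adjusted p = 0.0549; adjusted p = 0.679 with an estimated correlation and 0.0466 with the donor block). The inhibitory receptor gene TIGIT rose by 2.46. Of 24 glycolysis genes 0 were called, and 0 after median centring (adjusted p = 0.693). With the donor block 5 more lists passed. They were amino acid transport (median 0.28, adjusted p = 0.0482), heat shock genes (0.44, adjusted p = 0.0395), B cell markers (−0.79, adjusted p = 0.00887), monocyte markers (−0.60, adjusted p = 0.0238) and mitochondrially encoded genes (−0.24, adjusted p = 0.0103). Without the block none of them passed, and in this order the adjusted p was 0.679, 0.679, 0.620, 0.679 and 0.679 with an estimated correlation.

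Over all genes 1681 differed between low-dose IL-15 and fresh cells, 1335 higher and 346 lower, and 1331 after median centring, 1020 higher and 311 lower. The count was 338 without replicate 1, 782 without replicate 2, 962 without fresh replicate 1 and 1110 without low-dose IL-15 day 1 replicate 1. Lower genes alone numbered 194 without fresh replicate 3 and 205 without replicate 3.

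Cells at day 6 after 18/12/TxM were compared with day 1 to follow the response after the protein had been washed away. IFNG went from 17.06 ± 0.35 (SD, n = 3) to 6.79 ± 0.57 (SD, n = 3) in log2 CPM, a log2 fold change of −10.26 (limma adjusted p = 4.47e-08), and the chemokine CCL1 (−7.91), CSF2 (−6.13), LTA (−5.37), RGS16 (−5.23), TNFRSF9 (−5.20), CXCL10 (−5.18), EBI3 (−5.05) and IL2RA (−4.64) fell with it. CD52 was back at 9.23 ± 0.29 (SD, n = 3), a rise of 5.56, beside TC2N (6.69), CXCR3 (6.00), DPEP2 (5.85), FCMR (5.78), FCRL6 (5.68), the nucleic acid sensor ZBP1 (4.96), the cannabinoid receptor CNR2 (4.81) and granzyme K, GZMK (4.69). GZMB fell by 2.70, PD-L1 (CD274) had a log2 fold change of −3.66 and LAG3 one of −2.14.

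The growth and signalling lists fell. Of 33 ribosome biogenesis genes 2 rose and 25 fell (adjusted p = 3.07e-40), and of 26 unfolded protein response genes 2 and 19 (adjusted p = 5.54e-27). NF-kB targets had 2 rises and 18 falls among 31 (2 and 17 adjusted over the list alone, adjusted p = 4.7e-23), and heat shock genes 1 and 13 among 20 (adjusted p = 3.67e-22). Glycolysis had 1 rise and 15 falls among 24 (adjusted p = 4.34e-22), and STAT5 and STAT3 targets 2 and 15 among 25 (adjusted p = 9.62e-20). Cholesterol and fatty acid synthesis had 4 rises and 17 falls among 30 (3 and 17 adjusted over the list alone, adjusted p = 1.47e-19). Amino acid transport had 6 and 13 among 23 (adjusted p = 2.21e-14), and cytokines and chemokines 8 and 13 among 32 (adjusted p = 4.85e-14). After median centring these 9 lists had 33, 26, 30, 20, 24, 23, 28, 19 and 19 falls and at most 1 rise each. Apoptosis regulators had 8 rises and 7 falls among 27, with a median of 0.15 and a mean of 0.17, but 3 and 21 after median centring and 7 and 8 with well-expressed centring, and the test was down (adjusted p = 4.11e-06). These 10 calls held with an estimated correlation. With well-expressed genes alone 4 of them were lost: STAT5 and STAT3 targets (median −0.16, adjusted p = 0.154), amino acid transport (−0.80, adjusted p = 0.109), cytokines and chemokines (0.65, adjusted p = 0.603) and apoptosis regulators (−0.43, adjusted p = 0.393). NOP16 (−2.21), HYOU1 (−1.98), HSP90AB1 (−2.41), HK2 (−3.11), PKM (−2.58), MSMO1 (−1.43), PSAT1, an enzyme of serine synthesis (−3.88), TRAF1 (−2.96) and CDKN1A (−3.92) fell.

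Of 26 quiescence genes 22 rose and 2 fell, 11 and 7 after median centring (adjusted p = 0.0416; adjusted p = 0.531 with an estimated correlation). KLF2 was at 4.53, TCF7 at 4.24 and IL7R at 4.28. CD56 dim genes had 15 rises and 2 falls among 21, 9 and 5 after median centring (adjusted p = 0.970), with FGFBP2 at 3.58. CD56 bright genes had 12 and 1 among 20, 7 and 6 after median centring (adjusted p = 0.908). For several lists the median and mean were above 0 while camera placed the list below other genes, and median centring turned the balance. Cytotoxic granule genes had 10 rises and 4 falls among 21 (9 and 4 adjusted over the list alone), but 3 and 15 after median centring and 7 and 5 with well-expressed centring (adjusted p = 0.00399; adjusted p = 0.405 with an estimated correlation). Activating receptors had 18 and 8 among 30, but 4 and 13 after median centring and 16 and 8 with well-expressed centring (adjusted p = 0.00124; adjusted p = 0.362 with an estimated correlation). CD160 (4.62) and CD27 (3.82) rose among them and SLAMF1 (−3.46) fell. Lymphocyte transcription factors had 20 and 8 among 36, but 6 and 20 after median centring and 19 and 11 with well-expressed centring (adjusted p = 0.0115; adjusted p = 0.398 with an estimated correlation). Immediate early genes had 12 and 5 among 24, but 2 and 12 after median centring and 11 and 6 with well-expressed centring (adjusted p = 0.00521; adjusted p = 0.486 with an estimated correlation). Cell cycle genes had 29 rises and 5 falls among 48, with TOP2A (3.23), BIRC5 (2.92) and NUSAP1 (2.88) among the rises, 13 and 23 after median centring and 27 and 7 with well-expressed centring (adjusted p = 0.703). Interferon-stimulated genes had 30 and 4 among 45, 5 and 18 after median centring and 29 and 4 with well-expressed centring (adjusted p = 0.698). Oxidative phosphorylation had 7 and 8 among 31 (7 and 7 adjusted over the list alone), and 0 and 31 after median centring (adjusted p = 1.91e-10; adjusted p = 0.149 with an estimated correlation). Ribosomal protein genes had 11 and 7 among 36 (11 and 5 adjusted over the list alone), with a median of 0.18 and a mean of 0.19, but 0 and 35 after median centring and 9 and 10 with well-expressed centring, and the test was down (adjusted p = 6.63e-05; adjusted p = 0.486 with an estimated correlation). Mitochondrially encoded genes (median 0.18, mean 0.23) had 0 calls among 13, 0 rises and 13 falls after median centring, 0 and 0 with well-expressed centring, and a test that was down (adjusted p = 0.0102; adjusted p = 0.624 with an estimated correlation). Plasma cell markers (median 1.29, mean 0.25) had 2 rises and 2 falls among 7, 1 and 3 after median centring, 2 and 2 with well-expressed centring, and a test that was down (adjusted p = 0.0293; adjusted p = 0.483 with an estimated correlation).

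Between these days 15704 genes differed, 14486 higher at day 6 and 1218 lower, 11225 after median centring, 3716 higher and 7509 lower, and 15057 with well-expressed centring, 13401 higher and 1656 lower, so the larger direction depended on the scaling. Among well-expressed genes 1056 were higher and 591 lower on the deposited scale. Day 6 was reached with 18/12/TxM alone, so time in culture and treatment are not separable.

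Cells at day 6 were compared with fresh cells to find what set them apart after the acute response. CXCR6 (chromosome 3, 45940933 to 45948353), a chemokine receptor of tissue-resident lymphocytes, went from 1.94 ± 0.38 (SD, n = 3) to 7.44 ± 0.32 (SD, n = 3) in log2 CPM, a log2 fold change of 5.50 (limma adjusted p = 2.59e-06). IL2RA (4.86), CCR1 (4.69), GPR171 (4.07), IL23R (4.05), the ectonucleotidase ENTPD1 (4.02), CD200R1 (3.78), DPP4 (3.65), LAG3 (3.29) and CCR2 (3.27) were higher at day 6, and cell division genes rose, with CDK1 at 3.42, BUB1 at 2.99, TOP2A at 2.78 and AURKA at 2.45. RGS2 (−4.35), ZFP36 (−3.98), AREG (−3.95), SPON2 (−3.92), JUNB (−3.85), DUSP1 (−3.66), FCRL6 (−3.49) and ADGRG1 (−3.11) were lower. GZMB was at 11.56 ± 0.52 (SD, n = 3) against 11.51 ± 0.43 (SD, n = 3) in fresh cells (adjusted p = 0.880), and IFNG had a log2 fold change of 2.72 (adjusted p = 0.00675; 0.0631 after median centring, 0.0600 without replicate 1 and 0.0698 without replicate 2).

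Of 48 cell cycle genes 36 rose and 0 fell (41 and 0 adjusted over the list alone), with a median of 1.67, and 22 and 1 after median centring (adjusted p = 3.79e-11), a call that held with an estimated correlation but not with well-expressed genes alone (median 0.63, adjusted p = 0.222). Of 24 immediate early genes 3 rose and 14 fell, with a median of −1.30, and 1 and 17 after median centring (adjusted p = 3.39e-17; adjusted p = 0.0734 with an estimated correlation). CSRNP1 was at −2.94 and DUSP2 at −2.56. Of 21 CD56 dim genes 0 rose and 10 fell (0 and 11 adjusted over the list alone), and 0 and 15 after median centring (adjusted p = 2.25e-17; adjusted p = 0.0734 with an estimated correlation). FGFBP2 (−2.35), PRSS23 (−2.02) and the transcription factor gene ZEB2 (−1.76) were among them. CD56 bright genes had 8 rises and 1 fall among 20, 4 and 4 after median centring, 8 and 1 with well-expressed centring (adjusted p = 0.885). GZMK was at 2.14, KIT at 2.46, LTB at 2.30 and KLRC1, the gene of NKG2A, at 1.77. Cytokine receptors had 16 rises and 0 falls among 29, 3 and 5 after median centring, 14 and 1 with well-expressed centring (adjusted p = 0.241), with IL12RB2 at 2.44 and IL1RL1 at 3.01. Inhibitory receptors had 11 and 1 among 21, 6 and 5 after median centring (adjusted p = 0.555), with TIGIT at 1.98 and HAVCR2, the gene of TIM-3, at 1.75. Of 36 transcription factors 12 rose and 7 fell, 1 and 15 after median centring and 10 and 7 with well-expressed centring. Their median was 0.26 and their mean 0.15, but the test was down (adjusted p = 0.0141; adjusted p = 0.419 with an estimated correlation and 0.0595 with the donor block). EOMES was at 1.85, ZNF683, the gene of HOBIT, at −2.65 and RUNX3 at −1.44.

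Cytokines and chemokines had 13 rises and 2 falls among 32 (15 and 2 adjusted over the list alone), 3 and 2 after median centring (adjusted p = 0.534). Cytotoxic genes had 5 and 3 among 21 (5 and 5 adjusted over the list alone), 3 and 12 after median centring and 5 and 6 with well-expressed centring. Their median was −0.12 and their mean 0.07, and the test was down (adjusted p = 0.00605; adjusted p = 0.437 with an estimated correlation), with TNFSF10 at 2.57 and FASLG at 1.77. Quiescence genes had 2 rises and 8 falls among 26, 0 and 20 after median centring (adjusted p = 1.65e-09; adjusted p = 0.0831 with an estimated correlation), with CXCR4 at −2.31. NF-kB targets had 7 and 2 among 31, with a median of 0.15 and a mean of 0.12, but 0 and 12 after median centring and 4 and 3 with well-expressed centring, and the test was down (adjusted p = 0.01; adjusted p = 0.480 with an estimated correlation). Of 12 histone genes 0 rose and 8 fell, 0 and 9 after median centring (adjusted p = 5.52e-09; adjusted p = 0.0734 with an estimated correlation). Of 36 ribosomal protein genes 0 rose and 15 fell (0 and 17 adjusted over the list alone), 0 and 36 after median centring (adjusted p = 3.38e-23; adjusted p = 0.0831 with an estimated correlation). Of 13 mitochondrially encoded genes 0 rose and 5 fell (0 and 10 adjusted over the list alone), 0 and 13 after median centring (adjusted p = 5.8e-11; adjusted p = 0.233 with an estimated correlation). The unfolded protein response had 2 rises and 6 falls among 26, 0 and 19 after median centring (adjusted p = 1.39e-06; adjusted p = 0.149 with an estimated correlation). Oxidative phosphorylation had 4 and 5 among 31, 0 and 25 after median centring (adjusted p = 1.5e-05; adjusted p = 0.419 with an estimated correlation). Cholesterol and fatty acid genes had 6 and 4 among 30 (5 and 4 adjusted over the list alone), with a median of 0.09 and a mean of 0.04, but 0 and 12 after median centring and 5 and 5 with well-expressed centring, and the test was down (adjusted p = 0.00469; adjusted p = 0.419 with an estimated correlation). Plasma cell markers had 0 rises and 1 fall among 7, 0 and 2 after median centring, with a median of −1.31 (adjusted p = 0.00402; adjusted p = 0.419 with an estimated correlation). Monocyte markers had 0 and 1 among 17 (0 and 0 adjusted over the list alone), 0 and 3 after median centring, with a median of −0.12 (adjusted p = 0.00294; adjusted p = 0.480 with an estimated correlation). B cell markers, at a median of 0.08, passed with the donor block alone (adjusted p = 0.0424, test down), against an adjusted p = 0.480 with an estimated correlation.

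Over all genes 7605 differed between day 6 and fresh cells, 6797 higher and 808 lower, 5839 after median centring, 958 higher and 4881 lower, and 6665 with well-expressed centring, 5562 higher and 1103 lower, so the larger direction again depended on the scaling. Among well-expressed genes 579 were higher and 292 lower on the deposited scale. The count was 2088 without replicate 1, 2804 without replicate 2, 4376 without fresh replicate 1 and 4906 without 18/12/TxM day 6 replicate 2. Lower genes alone numbered 520 without 18/12/TxM day 6 replicate 1.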

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

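The 5 alternatives added after the data had been seen were centring on well-expressed genes, limma-voom on the recovered reads, IFNG left out of the totals, thinning to the smallest total, and well-expressed genes alone; the rest were planned. In all, 410 gene results were followed, of which 49 lost their call under at least 1 alternative and 0 that passed changed direction. The counts of calls for IL-12/15/18 and for 18/12/TxM against low-dose IL-15 were 10854 and 10767; they were 5763 and 6004 after median centring, 4980 and 5144 after quantile normalization and 5787 and 5856 with limma-voom. Quantile normalization also gave 7742 for day 6 against day 1 (15704) and 4814 for day 6 against fresh (7605). The stricter filter gave 10314 for day 6 against day 1, and array weights gave 4298 for low-dose IL-15 against fresh (1681). With well-expressed genes alone, fewer genes were tested, and the counts were 1627, 1619, 642, 1602 and 820 for IL-12/15/18 and 18/12/TxM against low-dose IL-15, low-dose IL-15 against fresh, day 6 against day 1 and day 6 against fresh. The test at the preset correlation made 78 list calls, of which 31 held with an estimated correlation, 26 with well-expressed genes alone and 18 with both. Lists of other cell types and of histone genes could not be tested with well-expressed genes alone, and their calls are counted as not held there. Well-expressed genes alone also made 5 new list calls. For 18/12/TxM against IL-12/15/18 these were cytokines and chemokines (median −0.26, adjusted p = 0.0191), cytotoxic granule genes (−0.13, adjusted p = 0.0132) and activating receptors (−0.10, adjusted p = 0.0176), each at an adjusted p = 0.959 with an estimated correlation over all genes. For day 6 against fresh they were cytokines and chemokines (1.29, adjusted p = 0.0285) and inhibitory receptors (1.09, adjusted p = 0.0481), each at an adjusted p = 0.761 with an estimated correlation over all genes. Except with well-expressed genes alone, where fewer genes enter, the cause was not tested.

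With the replicate block, the counts were 11327, 11190, 0, 2137, 16068 and 8226 in the order of the report, with 86 list calls; the pairing by donor changed the list calls given in the report and, among the genes followed, LYZ for day 6 against fresh (−1.87, adjusted p = 0.0217, and 0.182 without the block). The self-contained test fry had the opposite direction to camera for day 6 against day 1 in cytotoxic granule genes (median 0.17), activating receptors (1.34), lymphocyte transcription factors (0.88) and immediate early genes (0.79), since it tests the members' own direction and not their place among other genes. Leaving out 1 donor, or 1 library of the groups compared, gave 6443 to 11873 calls for IL-12/15/18 against low-dose IL-15, 6115 to 11627 for 18/12/TxM against low-dose IL-15, 0 to 2 for 18/12/TxM against IL-12/15/18, 338 to 1627 for low-dose IL-15 against fresh, 13930 to 15275 for day 6 against day 1 and 2088 to 6433 for day 6 against fresh. The r between the activated responses ran from 0.810 to 0.910, and list calls from 77 to 95. The donors and libraries that moved a total count of calls by over 1.5 times stand beside it in the report. For the counts of higher and of lower genes the report does not list all such settings. Depth was lowest at day 6, and thinning all libraries to the smallest total moved no count of calls by over 1.5 times. The list tests have no counterpart with robust eBayes and were not repeated without single libraries.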

Other observations

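The tests of IFNG's share, of a single scale factor and of depth in the first pattern weighed here were chosen only after the result was seen; the others were chosen before. The course over the 5 groups differed from gene to gene. The chemokine receptor gene CXCR6 had a mean log2 CPM of 1.94 in fresh cells, 4.99 with low-dose IL-15, 5.67 and 5.59 after IL-12/15/18 and 18/12/TxM, and 7.44 at day 6. EOMES, the gene of a T-box factor of NK cells, stood at 6.21, 7.39, 8.08, 7.97 and 8.05 in the same order. KIT stood at 3.44 and 6.19 in fresh and low-dose cells, at 2.03 and 2.10 in the activated groups and at 5.91 at day 6, and ZFP36 at 9.08, 5.63, 3.21, 2.60 and 5.10. LAG3 stood at −0.04 and −0.50, then at 5.50 and 5.39, and at 3.25 at day 6, and GZMB at 11.51, 11.68, 14.51, 14.27 and 11.56.

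Genes called in low-dose IL-15 against fresh cells were often called at day 6 against fresh cells too. Of the 1335 genes higher with low-dose IL-15 and the 6797 higher at day 6, 1226 were shared, against 469 for independent lists, and of the 346 and 808 lower, 259 were shared, against 14.4. The comparisons share the fresh libraries. In 100 draws, unchanged groups and the controls they share were all simulated from the spread within groups, and they shared at most 11 higher and 1 lower. Groups without any effect have few calls to share, so these simulated counts cannot weigh the overlap. Across genes the covariance of the log2 fold changes was 0.198, within the simulated range (median 0.128, 0.0348 to 0.250), so it does not set a shared effect apart from the shared controls. The 3 fresh libraries cannot be split into parts of 2, so part of the excess may come from the shared controls. The genes shared as higher were 258 without replicate 1, 572 without replicate 2 and 731 without fresh replicate 1, and those shared as lower 56, 112 and 137, with 151 without replicate 3 and 160 without fresh replicate 3. After median centring 255 and 285 were shared, against 50.5 and 78.4 for independent lists, and with limma-voom 540 and 422, against 238 and 88.9. MALAT1, a nuclear RNA, made up 2.98%, 2.26%, 0.684%, 0.617% and 2.20% of the reads in the 5 groups, and mitochondrially encoded genes 5.32%, 4.78%, 2.99%, 2.95% and 4.0%.

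Genes of low abundance were lower after activation at day 1 and higher at day 6, and the tables argue against 3 explanations of this. IFNG taking part of each activated library is excluded as the whole cause, since genes under a log2 CPM of 0 still had a median of −1.08 with IFNG left out; a single scale factor per library is excluded since these genes exceeded those of 8 and over by 2.87 in log2 fold change between day 6 and day 1; and unequal depth is excluded since the median was 3.08 after thinning. Reads from genes that NK cells do not express remain open. Of 129 genes of lens, cornified skin, liver, testis and neurons, 65 had at least 10 reads and a mean CPM under 1, and so were chosen to be weak. From reads summed per group, their median log2 ratios against low-dose IL-15 were −1.05 (−1.36 to −0.77) for IL-12/15/18 and −1.06 (−1.34 to −0.68) for 18/12/TxM. For day 6 against day 1 the median was 2.78 (2.38 to 3.10). All lay within 0.211 of the tested genes under 0. The ranges come from 1000 resamplings of these genes and hold no spread between donors. The summed CPM of these genes was 23.3 ± 5.12, 18.6 ± 5.18, 8.38 ± 3.44, 9.12 ± 3.02 and 53.4 ± 4.93 (SD, n = 3) in fresh, low-dose, IL-12/15/18, 18/12/TxM day 1 and day 6 libraries. A candidate explanation is therefore a background of reads, such as from DNA or unspliced RNA, whose share falls when cells hold more mRNA. For day 6 against fresh cells the median log2 ratio of these genes was 1.18 (1.03 to 1.43). Such a background would thus have to take a larger share at day 6 than in fresh cells, and why it would was not tested. RNA per cell was not measured here. A true rise of many weak genes by day 6, which the design names through time in culture, was not tested.

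Abundant transcripts of other blood cells were lower at day 6 than in fresh cells, and an immunoglobulin gene, IGHA1, had a mean log2 CPM of 6.67 in fresh cells, 5.64 with low-dose IL-15 and −3.34 at day 6. Of 22 such genes, fixed before the test, 19 were lower at day 6, with a median log2 fold change of −4.06 (−4.64 to −2.06). This range comes from 1000 resamplings of the 22 genes and holds no spread between donors. The median was −3.98 from summed reads with genes under 3 reads set to 3, −4.93 after quantile normalization, and −1.96 and −1.42 with pseudocounts of 1 and 4. It was −2.73 without fresh replicate 1, −2.83 without replicate 1 and −3.26 without 18/12/TxM day 6 replicate 2. The 3924 genes of like fresh level had a median of 0.60, a rise that the 22 genes did not share. Their fall already says so, and this comparison adds no test of its cause. Of the 22, 13 passed as lower and 0 as higher, 17 as lower with the donor block, 16 with array weights and 15 with only the 2 groups (the last 2 settings with 1 higher), but 8 without replicate 2 or without 18/12/TxM day 6 replicate 2, 7 without fresh replicate 1 and 4 with limma-voom; 12 of the 13 lost their call under at least 1 alternative, in 44 lost calls that were negative in 44 (−10.05 to −1.19) and had a larger SE in 41, such as IGHA1 at −10.01 (SE 1.58, adjusted p = 0.000271) and −10.05 (SE 5.70, adjusted p = 0.173) with limma-voom. RNA of plasma cells and red cells lost during culture may account for the fall: 11 of 11 plasma cell genes (median −5.44) and 3 of 3 red cell genes (−2.81) were lower. Of 8 myeloid genes 5 were (−1.22), and FCN1 (0.04), VCAN (0.85) and CST3 (0.68) were not. The 11 plasma cell genes were immunoglobulin genes and JCHAIN. For day 6 against fresh cells the plasma cell marker list of the report had a smaller median fall and few calls. The B cell and monocyte marker lists had medians that hardly moved. From 18/12/TxM day 1 to day 6 these 11 plasma cell genes fell further, such as IGHA1 from a mean log2 CPM of 4.01 to −3.34. The plasma cell marker list of the report had as many rises as falls between these days, and a positive median. Red cell genes rose between these days on the deposited scale: HBB from −0.47 to 1.85, HBA1 from −2.23 to −0.63 and HBA2 from −2.14 to −1.05. The median tested gene rose by 1.73 then, more than HBA1 or HBA2 did, so the rise of HBA1 and HBA2 depended on the scaling. Loss alone does not give such a rise, but genes of low abundance rose then as well, so for red cells the question stays open. A CD56+ CD3− isolation should remove these cells, and 12 of the 22 genes are also in the marker lists of the report and 0 in the NK cell lists.

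The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, so a share under 0.05 is out of reach. The real split gave 10854, 10767, 1681, 15704 and 7605 calls in the 5 comparisons other than 18/12/TxM against IL-12/15/18, and the highest of the other splits gave 0 in each, so 1 of the 10 splits reached the real count. For 18/12/TxM against IL-12/15/18 the real split gave 0 calls, which 10 of the 10 splits reached, and the highest of the others gave 122. That count points to a structure of the samples. The split parted 1 donor's pair and kept the other pairs whole on opposite sides, but of the 5 more splits of this kind 1 gave 2 and 4 gave 0, so donor was not shown to be the structure. The other splits that parted 3 pairs, as the real one does, gave 0.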
